A study of Mus musculus with 12 samples.

How the data were processed

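RNA was measured in 12 libraries of sorted mouse iNKT cells, 100 cells each. Per the labels, molecular barcodes (UMIs) sat in the oligo-dT reverse transcription primer, a common sequence was joined by template switching, PCR followed, and ERCC spike-in RNA went into each tube. Per the submitters' processing notes, reads were mapped with STAR (version not given) to mm10. The counting step, the annotation and the scaling formula are not stated.

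The deposited table holds a signal per gene and library, made by the authors, with 24781 gene symbols and 0 ERCC rows. Each value was a molecule count times a constant of its library: every nonzero value was a multiple of 0.01 of the column's most frequent value, and 94.3% to 95.9% were whole multiples of it (tolerance 1e-06). The 6 thymus columns each summed to 26890.5 units and the 6 lung columns each to 19342.9, a ratio of 1.39. These were not raw counts, so the test planned for normalized values was used in place of the test planned for counts. Molecules per library were recovered by dividing by the constant and ranged from 29696 to 71789. Against a group with no molecule of a gene, folds were bounded with a floor of 3 molecules over the group, and intervals on ratios of molecules were exact 95% binomial intervals. ERCC molecules could not be used for scaling.

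Samples were grouped by tissue and CD244 from the labels. The following were fixed before the data were examined: the groups, the 6 comparisons, the tests, the lists, the rule for named genes and the first set of other settings. Values were taken as log2(value + 1). The 5138 genes that exceeded 1 in at least 3 libraries were tested. One limma 3.58.1 model (trend and robust options, R 4.3.3) with 4 groups gave all comparisons: CD244-positive minus CD244-negative in thymus, in lung, and averaged over both; the difference of these effects between tissues (interaction); and lung minus thymus within each subset. P-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. An exact test of 3 against 3 libraries cannot go below 0.1.

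The lists numbered 28, of which 22 had at least 4 tested members. Each was tested with camera at a preset correlation of 0.01 and adjusted over the lists within a comparison, with an estimated correlation and the rotation test fry as alternatives. Members called were also counted with adjustment over the list alone. The overlap of thymus and lung calls was compared with independent lists by a one-sided hypergeometric test. Standard errors of the correlations across genes were from a jackknife over libraries.

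Genes were named by rule: up to 12 higher and 12 lower per comparison with the smallest p among those past the threshold with groups that did not overlap (8 per direction for tissue comparisons, 10 in all for the interaction), the gate genes Cd244, Cxcr6 and Klrb1c, and up to 4 members of each list with the smallest p. Not all are printed, and 1 list result for lung against thymus in CD244-negative cells is not reported here. Positions came from GENCODE M21, in which 24197 of 24781 symbols, and 5083 of the 5138 tested, matched 1 gene.

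That first set was quantile normalization, no filter, a stricter filter (a value of 5 in 3 libraries), sample quality weights, pseudocounts of 0.5 and 5, a replicate block, only the libraries compared, and each library left out in turn. Settings chosen after seeing the data were a common total of 23117 units, molecules thinned to the shallowest library, values scaled to the T cell receptor complex genes, lung CD244-positive library 1 alone, and edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) on recovered molecules rounded to whole numbers. The edgeR fit used 9 libraries. The other 3, 1 each of thymus CD244-positive, thymus CD244-negative and lung CD244-positive, were left out because their smallest value is a fraction of a molecule, so that whole steps could not be checked from it. An edgeR fit on all 12 libraries was also run and is not reported.

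The test was tried on simulated data with 100 changed genes at each size. In thymus it recovered 18% of 2-fold and 86% of 4-fold changes and called 2 unchanged genes. In lung it recovered 34% and 96% and called 11 unchanged genes. Every gene and group was drawn with 1 common dispersion (0.0109). Changed genes were taken from those expecting at least 3 molecules in the shallowest library compared. The chi-square per degree of freedom between real replicates was 2.28 to 2.35 in lung CD244-positive and 1.14 to 1.46 in the other groups. The lung figures do not cover that larger spread.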

Results

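Gene expression was profiled in invariant natural killer T (iNKT) cells, T lymphocytes whose receptor recognises lipid antigen on CD1d, isolated from the thymus or the lung of mice aged 6 weeks. Each library was made from 100 cells sorted as TCRbeta-positive, NK1.1-positive, CD1d-tetramer-positive and CXCR6-positive. The CD244-positive fraction is named the C2 subset and the CD244-negative fraction the C1 subset. The 12 libraries form 4 groups of 3: thymus CD244-positive, thymus CD244-negative, lung CD244-positive and lung CD244-negative. The labels call the replicates independent library preparations and do not name separate animals, so the p-values measure only the spread between these samples, which may be technical.

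The number of molecules recovered per library was 56615 to 71789 in thymus CD244-positive, 60120 to 67478 in thymus CD244-negative, 42520 to 51436 in lung CD244-positive and 29696 to 32196 in lung CD244-negative cells. The mean number of genes with a molecule was 7273 ± 218, 7346 ± 185, 7372 ± 133 and 5777 ± 138 in the same order (SD, n = 3). A count of 3 molecules in a library corresponded to 1.12 to 1.42, 1.20 to 1.34, 1.13 to 1.36 and 1.80 to 1.95 deposited units in the same order. Intervals and floors cover counting error only. Fold changes are on the scale of log2(value + 1) and understate the changes of genes with low values.

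The sort markers were seen at low counts. Cd244, which encodes the receptor that defined the subsets, had 8, 1 and 4 molecules in the thymus CD244-positive libraries and none in the thymus CD244-negative libraries, at least 4.39-fold more against a floor of 3 molecules over the group. In lung it had 1, 1 and 0 molecules in the CD244-positive libraries and none in the CD244-negative libraries, so a difference was not detectable at this depth. Cxcr6, a chemokine receptor within the gate, had 101 molecules in thymus CD244-positive and 96 in thymus CD244-negative cells. In lung it fell in CD244-positive cells (log2 fold change -1.89 ± 0.40 SE, limma adjusted p = 0.00163), where the libraries held 15, 1 and 1 molecules, against 10, 13 and 15 in CD244-negative cells. Klrb1c, the gene of the NK1.1 antigen, had log2 fold changes of 0.20 ± 0.24 in thymus and -0.59 ± 0.24 in lung, neither past the threshold.

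The first comparison asked how the CD244-positive and CD244-negative subsets differ in thymus. CD244-positive cells held more RNA of cytotoxic, Ly49 receptor and circulation genes and less RNA of genes that mark NKT2 and early thymic iNKT cells. S100a6, a calcium-binding protein gene (chromosome 3, 90612882 to 90624181, build mm10), had 25.4 ± 4.27 units in CD244-positive against 2.98 ± 1.08 in CD244-negative cells (SD, n = 3). Ccl5, a chemokine gene (chromosome 11, 83525778 to 83530518), had 91.6 ± 5.33 against 6.60 ± 0.715 units. Gzma, the gene of the granule protease granzyme A (chromosome 13, 113093825 to 113100981), had 13.7 ± 2.01 against 0.485 ± 0.839 units. Icos, a co-stimulatory receptor gene (chromosome 1, 60977927 to 61000320), had 3.17 ± 0.712 against 9.0 ± 3.04 units. Lef1, a transcription factor gene of early T cells (chromosome 3, 131110471 to 131224356), had 0.516 ± 0.567 against 3.88 ± 1.03 units.

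The egress and circulation list was called up in thymus CD244-positive cells (camera adjusted p = 3.37e-15), with 6 of 20 tested members higher (7 adjusted over the list alone), 14 not past the threshold and a median log2 fold change of 0.48. Among them were S100a6 (log2 fold change 2.75 ± 0.29 SE, adjusted p = 2.34e-11), and S100a4 (2.90 ± 0.38, 3.91e-08). The others named were the intermediate filament gene Vim (2.0 ± 0.28, 3.88e-07), Ahnak (1.36 ± 0.20, 1.92e-06) and Klf2, a transcription factor that drives the egress receptor S1pr1 (1.96 ± 0.36, 0.000208). Their list summed to 65.6 ± 2.65 molecules per 10000 against 32.2 ± 1.70 (SD, n = 3).

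Cytotoxic effector genes summed to 85.8 ± 1.51 against 43.1 ± 0.799 molecules per 10000, with 2 of 13 tested members higher (4 adjusted over the list alone; camera adjusted p = 7.35e-09). Most of the difference in the sum came from Ccl5, and the median log2 fold change of the list was 0.14, with 8 members above and 5 below 0. The members past the threshold were Gzma (3.43 ± 0.38, adjusted p = 9.92e-11) and Ccl5 (3.61 ± 0.34, adjusted p = 0.000208). Gzmb, the granzyme B gene, had a log2 fold change of 0.97 ± 0.27 and did not pass (adjusted p = 0.120). Of 5 tested Ly49 receptor genes, which encode MHC class I receptors of NK cells, 2 rose (5 adjusted over the list alone; camera adjusted p = 1.23e-11). Of the nonzero values of Ly49 genes 48.2% were not whole molecules, against 4.45% over all tested genes, which makes the values of single Ly49 genes less certain. The genes that rose were Klra5 (2.29 ± 0.35, adjusted p = 3.95e-06) and Klra1 (1.40 ± 0.35, adjusted p = 0.0325). Of 16 other NK receptor and adaptor genes, 2 rose (3 adjusted over the list alone; camera adjusted p = 9.27e-07). They were the signalling adaptor gene Fcer1g (2.27 ± 0.36, adjusted p = 8.06e-06) and Klre1 (1.37 ± 0.33, adjusted p = 0.0281). The NK cell marker list summed to 5.58 ± 0.347 against 2.68 ± 0.129 molecules per 10000 in thymus, and to 4.36 ± 1.19 against 1.53 ± 0.248 in lung. Of its 4 tested members, 3 of which other lists also hold, 1 passed in thymus. Of 17 NKT1 marker genes, Ccl5 and Cd7 rose (1.31 ± 0.28 for Cd7, adjusted p = 0.00468), with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.93e-07). The chemokine and cytokine list was called up (camera adjusted p = 0.00157) through Ccl5, 1 of 7 members (2 adjusted over the list alone), while its median log2 fold change was -0.15.

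The NKT2 marker list fell to 11 ± 0.525 from 22 ± 2.44 molecules per 10000 (camera adjusted p = 9.39e-10), with 2 of 10 members lower (4 adjusted over the list alone). The lower members were Icos (log2 fold change -1.23 ± 0.28, adjusted p = 0.0141) and Izumo1r, the gene of a folate receptor of T cells (-1.69 ± 0.38, adjusted p = 0.00956). The list of NKT0 and early thymic stage genes fell (camera adjusted p = 0.000312), with Lef1 lower (-1.73 ± 0.37, adjusted p = 0.00586), 1 of 7 members (3 adjusted over the list alone). Ly6a, which encodes the surface antigen Sca-1, fell as well (-1.45 ± 0.36, adjusted p = 0.0305). Also higher were Ifitm2, an interferon-induced membrane protein gene with 15 molecules against none (at least 5.07-fold, adjusted p = 0.0213), Sp4 (1.73 ± 0.41, adjusted p = 0.0205) and Ifngr1 (0.85 ± 0.21, adjusted p = 0.0281). So were Efhd2 (1.12 ± 0.28, adjusted p = 0.0305) and the galectin gene Lgals1 (1.11 ± 0.28, adjusted p = 0.0374), both named after their values were seen. The lists of T cell receptor complex (camera adjusted p = 0.179), immediate early (0.702), cell cycle (0.134) and myeloid genes (0.781) were not called. The myeloid markers summed to 0.994 ± 0.0592 against 0.971 ± 0.317 molecules per 10000.

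In all, 17 genes rose and 4 fell in thymus at an adjusted p under 0.05 among 5138 tested genes. With edgeR on 9 libraries 12 genes were higher and 0 lower (86 of 1154 genes had an unadjusted p under 0.05), and of the NKT2 and early stage lists 0 of 6 and 0 of 4 members passed it (4 and 1 at an unadjusted p under 0.05). In limma 305 had an unadjusted p under 0.05, where chance gives 256.9. All 3 libraries of a group lay on 1 side of the other 3 for 11.9% of all tested genes, which chance gives for 10%. All 9 list calls held with an estimated correlation (NK cell markers had the largest adjusted p, 0.0397 with an estimated correlation). S100a6, Gzma, S100a4, Vim, Ahnak, Klra5, Fcer1g, Ccl5 and Klf2 stayed past the threshold whichever library was left out. Gzma missed it with edgeR (adjusted p = 0.0518) and with a pseudocount of 5 (adjusted p = 0.0743). The count of 21 was 13 without CD244-positive library 2, 11 without CD244-positive library 3, 13 without CD244-negative library 1 and 10 without CD244-negative library 2. Without CD244-positive library 3 or CD244-negative library 2, Icos (adjusted p = 0.188, 0.344), Lef1 (0.164, 0.117), Izumo1r (0.300, 0.122), Ly6a (0.473, 0.273) and Sp4 (0.244, 0.387) no longer passed. Without CD244-negative library 3, Icos and Izumo1r (adjusted p = 0.0767 each) did not pass. Ifitm2 (largest adjusted p = 0.184), Ifngr1 (0.327), Klre1 (0.201) and Klra1 (0.418) missed the threshold without any 1 of the 6 thymus libraries, and Ly6a and Sp4 without 5 of them. Cd7 missed it without CD244-positive library 1 (0.0599), CD244-positive library 3 (0.0523) or CD244-negative library 1 (0.173).

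**Figure D1:**
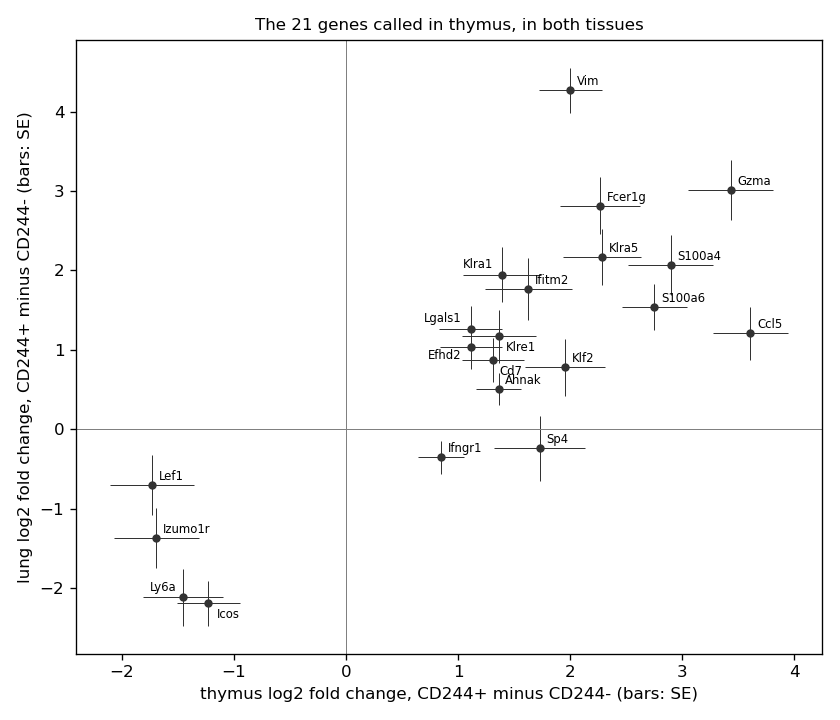
Log2 fold changes of CD244-positive minus CD244-negative cells in thymus (x axis) and lung (y axis) for the 21 genes called in thymus, with standard errors as bars. In lung 19 of the 21 lie on the same side of 0 as in thymus, and Sp4 (-0.24) and Ifngr1 (-0.35) lie on the other side.

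The same comparison in lung separated the subsets by many more genes, and the largest differences were in genes of macrophages and of antigen presentation. Apoe, a lipoprotein gene abundant in macrophages (chromosome 7, 19696109 to 19699188), had 324 molecules in lung CD244-positive and none in lung CD244-negative libraries, at least 69.6-fold more. Cd74, the gene of the MHC class II invariant chain (chromosome 18, 60803848 to 60812652), had 473 molecules against 1, a ratio of their shares of all molecules of 305 (95% counting interval 54.4 to 12065). Vim rose to 34.2 ± 3.05 from 0.845 ± 0.380 units (SD, n = 3), a log2 fold change of 4.27 ± 0.28 (SE, limma adjusted p = 1.24e-22). Among T cell genes, Icos fell to 4.82 ± 2.06 from 24.7 ± 2.68 units (-2.19 ± 0.28, adjusted p = 1.94e-09).

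All 10 tested myeloid markers rose in lung CD244-positive cells (10 adjusted over the list alone; camera adjusted p = 1.28e-24), and their sum was 58.0 ± 17.0 against 1.68 ± 0.656 molecules per 10000 (SD, n = 3). The mannose receptor gene Mrc1 was at least 28.8-fold higher, the complement genes C1qc, C1qb and C1qa at least 30.3-, 28.6- and 25.6-fold. The lysozyme gene Lyz2 was at least 15.4-fold higher and Cd14 at least 31.4-fold. Selenop, a selenoprotein gene (4.15 ± 0.39, adjusted p = 6.11e-15), and Cst3, the cystatin C gene (3.27 ± 0.32, adjusted p = 7.20e-14), rose with them. The 4 tested members of the B cell list all rose (4 adjusted over the list alone; 82.0 ± 39.7 against 0.542 ± 0.184 molecules per 10000). They were Cd74, H2-Aa, H2-Eb1 and H2-Ab1, genes of MHC class II antigen presentation that macrophages and dendritic cells express too. H2-Aa had 312 molecules against 1 (ratio 201, interval 35.8 to 7967). H2-Eb1 had 208 against 1 (134, 23.8 to 5320) and H2-Ab1 had 192 against 1 (124, 21.9 to 4912).

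Immediate early genes, which stimulation and tissue dissociation induce, summed to 109 ± 9.75 against 71.9 ± 2.18 molecules per 10000, with 11 of 24 higher (12 adjusted over the list alone; camera adjusted p = 6.25e-07) beside the rise in myeloid markers. Fos had 17.9 ± 0.650 against 1.05 ± 0.986 units (3.34 ± 0.40, adjusted p = 1.15e-10). Zfp36 had 12.1 ± 1.56 against 1.06 ± 0.400 units (2.68 ± 0.36, adjusted p = 9.70e-09). Beside the same rise in myeloid markers, egress and circulation genes rose with 9 of 20 higher (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.89e-07), among them S100a4 (2.07 ± 0.38, adjusted p = 2.08e-05) and S100a6 (1.54 ± 0.29, adjusted p = 3.91e-05). Of the cytotoxic genes, Gzma (3.01 ± 0.38, adjusted p = 1.17e-09), Gzmb (1.68 ± 0.27, adjusted p = 1.38e-06), Lamp1 and Ccl5 rose and Fasl fell (4 higher and 1 lower of 13, the same counts adjusted over the list alone). These calls too came beside the rise in myeloid markers, and Gzmb, Lamp1 and Fasl were not called in thymus. Ccl5 missed the threshold without thymus CD244-positive library 1 (adjusted p = 0.0526), thymus CD244-negative library 1, 2 or 3 (0.0895, 0.0796, 0.0739), lung CD244-positive library 1 (0.145) or lung CD244-negative library 3 (0.0532). Fasl missed it without lung CD244-positive library 1 or 3 (0.0655, 0.126) or lung CD244-negative library 2 (0.0892). Their list was called up (camera adjusted p = 0.00999), which was lost at an adjusted p = 0.102 with an estimated correlation. Ly49 receptor genes rose with 3 of 5 higher (4 adjusted over the list alone; camera adjusted p = 0.000328, and adjusted p = 0.0972 with an estimated correlation). Klra5 had 33 molecules against 1 (ratio 21.3, interval 3.56 to 865) and Klra1 rose by a log2 fold change of 1.95 ± 0.35 (adjusted p = 1.34e-05).

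Genes of the T cell receptor complex fell to 24.8 ± 6.33 from 49.2 ± 3.61 molecules per 10000 (SD, n = 3) in the same libraries, with 4 of 14 lower (9 adjusted over the list alone; camera adjusted p = 1.32e-06). Cd6 (-2.05 ± 0.35, adjusted p = 6.79e-06) and Thy1 (-1.72 ± 0.30, adjusted p = 7.08e-06), genes of T cell surface glycoproteins, fell most in it. NKT2 markers fell with 4 of 10 lower (7 adjusted over the list alone; camera adjusted p = 1.01e-05). Among them were Icos and Gata3, the Th2 transcription factor gene (-1.67 ± 0.30, adjusted p = 1.41e-05). The NKT1 list was called down with 3 higher and 6 lower of 17 (3 and 6 adjusted over the list alone; camera adjusted p = 0.00999, and adjusted p = 0.102 with an estimated correlation). Its sums did not separate the groups, at 98.9, 112 and 61.4 molecules per 10000 in CD244-positive libraries 1, 2 and 3 against 93.3, 101 and 105. Library 3 also had the lowest cytotoxic sum of the CD244-positive libraries (68.4 against 109 and 129). Lower members of the NKT1 list included the GTPase genes Gimap3 (-1.69 ± 0.23, adjusted p = 9.31e-09), Gimap6 (-1.97 ± 0.28, adjusted p = 3.04e-08), and Gimap4 (-1.35 ± 0.19, adjusted p = 4.98e-08). Others were Ly6c2 and the interleukin 2 receptor gene Il2rb (-1.02 ± 0.22, adjusted p = 0.000301). Cytokine receptor genes (3 of 14 lower, 3 adjusted over the list alone; camera adjusted p = 0.0257) and early stage genes (1 of 7 lower, 3 adjusted over the list alone; camera adjusted p = 0.00999) were called down. Both were lost, at an adjusted p = 0.165 and an adjusted p = 0.0604 with an estimated correlation. Satb1, a chromatin organiser of T cells (-1.66 ± 0.23, adjusted p = 1.85e-08), Ly6a (-2.12 ± 0.36, adjusted p = 4.40e-06), the cyclin gene Ccnd2 (-1.32 ± 0.20, adjusted p = 1.67e-07) and Ly6e (-1.26 ± 0.18, adjusted p = 7.26e-08) fell beside them.

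In lung 288 genes rose and 145 fell at an adjusted p under 0.05 (115 and 135 with the stricter filter, where fewer rose than fell), and 1007 had an unadjusted p under 0.05 (chance 256.9). Groups did not overlap for 21.4% of all tested genes (chance 10%). The calls of the myeloid, B cell, immediate early, egress, T cell receptor complex and NKT2 lists held with an estimated correlation. When values were scaled to the T cell receptor complex genes, 1199 genes were higher and 15 lower. With lung CD244-positive library 1 as the only library of its group, 162 genes were called, on the assumption that it varied like the other groups, so the count says nothing about spread in lung CD244-positive cells.

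**Figure D2:**
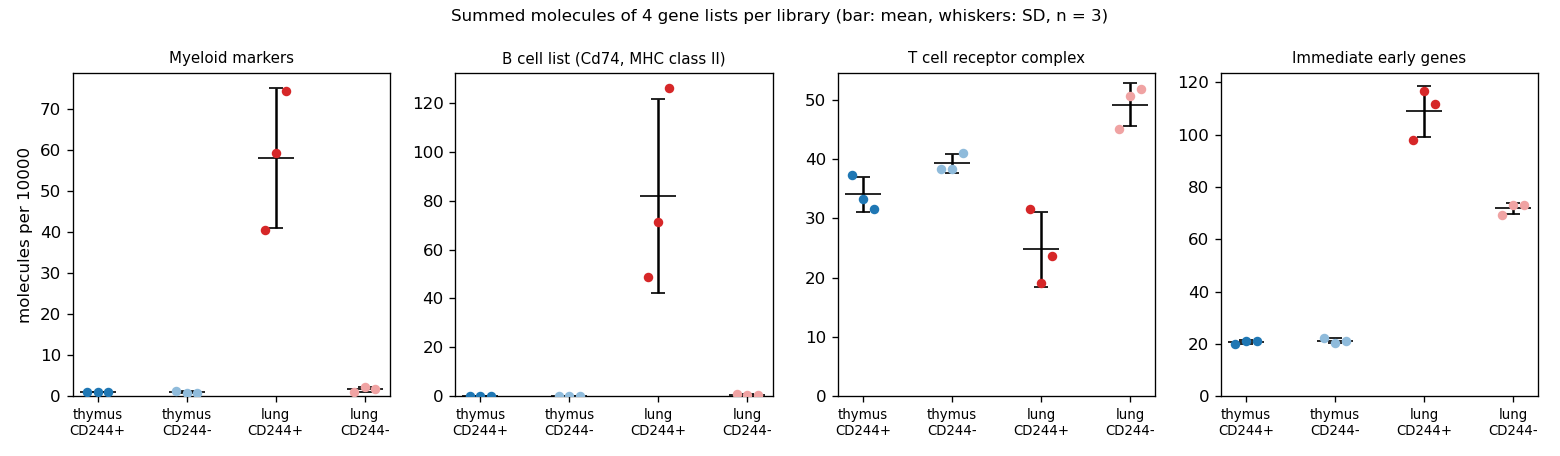
Summed molecules per 10000 in each library for the myeloid list, the B cell list (Cd74 and MHC class II genes), the T cell receptor complex list and the immediate early list in the 4 groups, with points for libraries, bars for means and whiskers for the SD (n = 3). The myeloid sums were 40.4 to 74.4 in the 3 lung CD244-positive libraries and at most 2.32 in the other 9.

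Over both tissues, with each weighted equally, the comparison asked how the subsets differ on average, which a difference in 1 tissue alone can also move. Vim (chromosome 2, 13573927 to 13582826) rose by a log2 fold change of 3.14 ± 0.20 (SE, 6 libraries against 6, limma adjusted p = 1.05e-23). Gzma (3.22 ± 0.27, adjusted p = 9.30e-17), S100a6 (2.15 ± 0.21, adjusted p = 5.50e-14) and S100a4 (2.48 ± 0.27, adjusted p = 7.54e-12) rose, as did Gzmb (1.32 ± 0.19, adjusted p = 1.81e-07) and Klra1 (1.67 ± 0.25, adjusted p = 2.42e-07). Icos (-1.71 ± 0.20, adjusted p = 1.47e-10), Satb1 (-1.17 ± 0.16, adjusted p = 5.01e-08) and Ly6a (-1.79 ± 0.25, adjusted p = 1.01e-07) fell, with Gimap4 (-0.94 ± 0.14, adjusted p = 1.63e-07) and Gimap3 (-1.0 ± 0.16, adjusted p = 2.46e-06).

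By list, 10 of 20 egress and circulation genes rose (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.87e-14). Likewise 4 of 5 Ly49 receptor genes rose (4 adjusted over the list alone; camera adjusted p = 4.73e-09) and 3 of 13 cytotoxic genes rose (5 higher and 1 lower adjusted over the list alone; 3.88e-06). NKT2 markers fell with 4 of 10 lower (8 adjusted over the list alone; camera adjusted p = 1.35e-10), and early stage genes with Lef1 and Satb1 lower of 7 (5 adjusted over the list alone; 0.000122). Genes of the T cell receptor complex fell with 3 of 14 lower (7 adjusted over the list alone; camera adjusted p = 3.08e-06), and interferon-stimulated genes with Ly6a and Gbp7 lower of 25 (3 adjusted over the list alone; 0.0116). Gbp7 passed only with thymus CD244-positive library 3 (adjusted p = 0.118 without it), thymus CD244-negative library 1 (0.0881) and lung CD244-positive library 2 (0.104) kept. The glycolysis list was called down with 0 of 13 members past the limma threshold (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 of 6 with edgeR; camera adjusted p = 0.0378). It was lost at an adjusted p = 0.0710 with an estimated correlation. In total 175 genes rose and 67 fell (81 and 76 with the stricter filter, 818 and 9 scaled to the T cell receptor complex genes), and 816 had an unadjusted p under 0.05 (chance 256.9). Eef1a1, a translation factor gene called lower (-0.29 ± 0.07, adjusted p = 0.00202), had a log2 fold change of 0.32 with values scaled to the T cell receptor complex genes. The myeloid list (10 of 10), B cell list (4 of 4), immediate early list (7 of 24), other NK receptor list (4 higher and 1 lower of 16) and NK cell list (1 of 4) were called up too (10, 4, 10, 5 higher and 2 lower, and 1 adjusted over the list alone). They and all lists above but glycolysis held with an estimated correlation. In thymus limma called 0 of 10 myeloid, 0 of 4 B cell list and 0 of 24 immediate early genes (0, 0 and 1 at an unadjusted p under 0.05; 0 of 6, 0 of 4 and 0 of 19 with edgeR). Over both tissues edgeR called 1 of 6, 0 of 4 and 1 of 19 of them (1, 0 and 3 at an unadjusted p under 0.05). Of the 10 tested myeloid markers, 2 had a molecule in thymus CD244-positive and 1 in thymus CD244-negative libraries. Of the 4 B cell list genes these numbers were 1 and 0. For genes with no molecule in thymus, edgeR has no thymus ratio to average, so its test cannot decide for them.

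The genes called between subsets in thymus and in lung overlapped more than independent lists would. The compared libraries were separate, but both sets of calls came from 1 model that shares the spread of each gene over all 12 libraries. Genes also differ in how easily they are called. The 2 lists are therefore not independent, and the hypergeometric p-values may be too small. The lung calls came from libraries in which the myeloid markers had risen to 58.0 from 1.68 molecules per 10000, and macrophages also express genes such as Vim, Fcer1g, S100a4 and S100a6. Of the 17 genes higher in thymus, 13 were also higher in lung, where 0.953 are expected of unrelated lists (one-sided exact hypergeometric p = 8.07e-14). Among them were Vim, Gzma, S100a6, S100a4, Fcer1g, Klra5, Klra1 and Ccl5. Of the 4 genes lower in thymus, Icos, Izumo1r and Ly6a were also lower in lung (0.113 expected, exact hypergeometric p = 8.63e-05). Izumo1r missed the threshold in lung without lung CD244-positive library 3 (adjusted p = 0.0728) or lung CD244-negative library 3 (0.117). Across all 5138 genes, which are not independent replicates, the fold changes of the tissues had a Pearson correlation of 0.123 (jackknife SE 0.0283) and a Spearman correlation of 0.0835 (SE 0.0293). Of the 21 thymus calls, 18 passed in lung in the same direction when adjusted over those calls alone. The 13 shared higher genes became 6 without thymus CD244-positive library 1, 8 without thymus CD244-positive library 2, 6 without thymus CD244-negative library 1, 7 without thymus CD244-negative library 2 and 8 without lung CD244-positive library 1. The 3 shared lower genes became 0 without thymus CD244-positive library 3, thymus CD244-negative library 2 or thymus CD244-negative library 3.

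The interaction tested whether the subset difference itself depended on the tissue. The 10 genes with the smallest p were Cd74, Apoe, H2-Aa, Selenop, H2-Eb1, H2-Ab1, Mrc1, C1qc, Cd14 and C1qb, genes of macrophages and antigen presentation that differed more between subsets in lung. Their limma adjusted p values ran from 1.35e-12 for Cd74 and Apoe to 1.57e-08 for C1qb (3 libraries in each of 4 groups). In thymus Apoe, H2-Aa, H2-Eb1, H2-Ab1, Mrc1, C1qc, Cd14 and C1qb had no molecule in any library of either subset. Vim differed more in lung as well (difference of log2 fold changes 2.27 ± 0.40 SE, adjusted p = 2.77e-05).

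All 10 myeloid markers and all 4 tested members of the B cell list were higher in the interaction (the same counts adjusted over each list alone; camera adjusted p = 1.23e-22 and 3.90e-19). So were 8 of 24 immediate early genes (10 adjusted over the list alone; 1 of 19 with edgeR, 4 at an unadjusted p under 0.05; camera adjusted p = 7.52e-07), among them Zfp36 (3.09 ± 0.51, adjusted p = 9.47e-06) and Egr1 (3.37 ± 0.57, adjusted p = 1.27e-05). NKT1 markers were lower with 4 of 17 (7 adjusted over the list alone; camera adjusted p = 8.56e-09). Ly6c2 (-1.59 ± 0.28, adjusted p = 2.65e-05), Gimap6 (-2.10 ± 0.39, adjusted p = 9.44e-05) and Gimap3 (-1.38 ± 0.32, adjusted p = 0.00371) were 3 of them. Klrc1, an NK receptor gene (-1.78 ± 0.39, adjusted p = 0.00129), the chemokine receptor gene Ccr2 (-1.65 ± 0.39, adjusted p = 0.00454) and Ifngr1 (-1.20 ± 0.29, adjusted p = 0.00569) differed the same way. Lists of the T cell receptor complex (1 of 14 lower, 3 adjusted over the list alone; camera adjusted p = 0.000477), cytokine receptors (2 of 14, 4 adjusted over the list alone; 0.00442), and chemokines and cytokines (1 of 7, 1 adjusted over the list alone; 0.0271) were called down. They were lost at an adjusted p = 0.0661, an adjusted p = 0.140 and an adjusted p = 0.106 with an estimated correlation. Their called members other than Ifngr1 depended on single libraries. Thy1 of the receptor complex missed the threshold without lung CD244-positive library 2 (adjusted p = 0.118) or lung CD244-negative library 3 (0.0692), and Ccl5 of the chemokines without thymus CD244-negative library 1 (0.0697) or 2 (0.0578). Of the cytokine receptors Il21r, named after its value was seen, missed it without any 1 of 9 libraries (largest adjusted p = 0.234), and Ifngr1 passed in each case. The cell cycle list was called up through Top2a (1 of 14, 1 adjusted over the list alone; camera adjusted p = 0.0237), lost at an adjusted p = 0.553 with an estimated correlation.

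In total 136 genes had a positive and 32 a negative interaction (58 and 46 with the stricter filter, 328 and 3 scaled to the T cell receptor complex genes), and 644 had an unadjusted p under 0.05 (chance 256.9). With edgeR on 9 libraries 21 genes passed. There 9 of the 10 leading genes, all but Selenop, missed the threshold with larger differences of log2 fold changes (8.19 for Cd74 and 9.64 for Apoe, adjusted p = 1.0 for each). Genes with no molecule in thymus give edgeR no thymus ratio, so its interaction test cannot decide for them. Of the myeloid markers 1 of 6 and of the B cell list 0 of 4 passed edgeR's interaction test (1 and 0 at an unadjusted p under 0.05), while in lung alone 6 of 6 and 4 of 4 passed it.

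The tissue comparison within the CD244-positive subset asked how lung cells differ from thymus cells. Lung libraries held more RNA of immediate early genes and of macrophage and antigen presentation genes, the latter with few or no molecules in thymus, and less RNA of ribosomal proteins and NKT1 markers. The myeloid list summed to 58.0 ± 17.0 against 0.994 ± 0.0592 molecules per 10000 and the T cell receptor complex list to 24.8 ± 6.33 against 34.1 ± 2.93. Dilution of T cell RNA by other RNA was not tested for this comparison. It and a lower level in the cells cannot be told apart for the T cell genes that fell. Apoe was at least 145-fold higher, H2-Aa at least 140-fold, H2-Eb1 at least 93.1-fold, H2-Ab1 at least 86.0-fold, C1qc at least 63.1-fold and Mrc1 at least 60.0-fold. Rpl32, a ribosomal protein gene (chromosome 6, 115805505 to 115808747), had 41.2 ± 6.30 units in lung against 160 ± 6.92 in thymus (SD, n = 3), a log2 fold change of -1.94 ± 0.12 (SE, limma adjusted p = 3.54e-25). Because the deposited columns summed to 19343 units in lung and 26891 in thymus, rescaling to a common total moved the median of all genes by 0.25 on the log2 scale. The totals themselves differ by 0.48 on that scale, and the added 1 damps the shift in genes with low values. Genes with high values carry nearly all of it. List counts on the common total are given beside the deposited ones, while fold changes of single genes are on the deposited values.

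Of 24 immediate early genes, 17 rose in lung CD244-positive cells (18 higher and 1 lower adjusted over the list alone; 18 on the common total; camera adjusted p = 1.97e-23). Their sum was 109 ± 9.75 against 20.6 ± 0.700 molecules per 10000. Fos was at least 59.1-fold higher, and Dusp1 (3.27 ± 0.33, adjusted p = 3.45e-14), Tnfaip3 (2.99 ± 0.34, adjusted p = 3.84e-12) and Junb (2.64 ± 0.26, adjusted p = 2.97e-14) rose. The myeloid list (10 of 10) and the B cell list (4 of 4) rose, with the same counts adjusted over the list alone and on the common total. The cell cycle list rose with 7 of 14 higher (8 adjusted over the list alone; 8 on the common total; camera adjusted p = 0.000159), lost at an adjusted p = 0.181 with an estimated correlation. The egress list was called up with 4 higher and 3 lower of 20 (4 and 3 adjusted over the list alone; 4 and 1 on the common total; camera adjusted p = 0.0470), lost at an adjusted p = 0.181 with an estimated correlation. Cxcr4, a chemokine receptor gene, rose (1.93 ± 0.32, adjusted p = 7.60e-07). Both tested lung epithelium markers rose, Cbr2 at least 11.2-fold and Scgb1a1, the secretoglobin gene of club cells, at least 7.16-fold. Within lung they did not behave alike. Cbr2 had 25 molecules in CD244-positive and 2 in CD244-negative libraries, a difference in the direction of the myeloid markers, while Scgb1a1 had 16 and 14. Scgb1a1 missed the threshold without lung CD244-positive library 2 (adjusted p = 0.0940).

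NKT1 markers fell with 13 of 17 lower (14 adjusted over the list alone; 8 on the common total; camera adjusted p = 2.24e-07). They included Fgl2 (-1.77 ± 0.26, adjusted p = 3.49e-08), Gimap3 (-1.44 ± 0.23, adjusted p = 3.23e-07) and Cd7 (-1.64 ± 0.28, adjusted p = 1.83e-06). Interferon-stimulated genes fell to 17.3 ± 1.10 from 36.5 ± 2.64 molecules per 10000, with 16 of 25 lower (17 adjusted over the list alone; 7 on the common total; camera adjusted p = 2.56e-05). Gbp7 (-2.16 ± 0.32, adjusted p = 5.38e-08) and Ifi203 (-1.90 ± 0.31, adjusted p = 6.64e-07) were among them. Id2, an inhibitor of E protein transcription factors (-2.43 ± 0.19, adjusted p = 6.02e-20), and the interleukin 7 receptor gene Il7r (-2.04 ± 0.23, adjusted p = 4.17e-12) fell. Cxcr6 (-2.64 ± 0.40, adjusted p = 9.75e-06) and Klrb1c (-2.28 ± 0.24, adjusted p = 3.49e-13) of the sort gate fell too. Genes of the T cell receptor complex (7 of 14 lower, 8 adjusted over the list alone; 3 on the common total; camera adjusted p = 0.00944) and Ly49 receptors (3 of 5, 3 adjusted over the list alone; 3 on the common total; 0.0166) were called down. They were lost at an adjusted p = 0.168 and an adjusted p = 0.223 with an estimated correlation. Of 77 ribosomal protein genes 75 fell (67 on the common total), with a median log2 fold change of -1.20 (-0.73 on the common total). Of their nonzero values 35.6% were not whole molecules, so values of single ribosomal protein genes are less certain. They made 14.5% ± 1.31 of molecules in lung against 25.9% ± 0.772 in thymus.

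Of all genes 271 rose and 494 fell on the deposited values, and 352 rose and 204 fell on the common total, with 475 called in the same direction on both. In all 1337 had an unadjusted p under 0.05 (chance 256.9). Groups did not overlap for 30.2% of all tested genes, which chance gives for 10%. Both figures are on the deposited values, where the lower lung total also moved genes down. The median log2 fold change of all genes was -0.27 there and -0.01 on the common total, so part of the excess over chance can come from the scaling.

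Within the CD244-negative subset, lung cells held more RNA of immediate early genes and less RNA of ribosomal proteins and interferon-stimulated genes than thymus cells. No myeloid marker passed the threshold, but the club cell gene Scgb1a1 had 14 molecules in lung and none in thymus (at least 9.86-fold, adjusted p = 0.000124). The lung epithelium list summed to 2.98 ± 1.21 against 0.0554 ± 0.0960 molecules per 10000. Vps37b, a gene of endosomal sorting (chromosome 5, 124004641 to 124032270), had 50.3 ± 7.43 units in lung against 4.79 ± 1.43 in thymus (SD, n = 3), a log2 fold change of 3.16 ± 0.24 (SE, limma adjusted p = 7.17e-20). Tnfaip3, an inhibitor of NF-kappaB signalling, had 21.1 ± 3.58 against 1.13 ± 0.571 units (3.39 ± 0.34, adjusted p = 5.82e-14). Junb, an AP-1 transcription factor gene, had 30.0 ± 5.0 against 3.81 ± 1.78 units (2.74 ± 0.26, adjusted p = 1.40e-14). Rps27 (chromosome 3, 90212522 to 90213651) fell to 62.9 ± 3.22 from 354 ± 47.8 units (-2.47 ± 0.10, adjusted p = 4.78e-38).

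Immediate early genes rose with 7 of 24 higher and Dusp2, named after its value was seen, lower (8 higher and 2 lower adjusted over the list alone; 9 higher and 0 lower on the common total; camera adjusted p = 5.36e-10). Fosl2 (2.86 ± 0.37, adjusted p = 1.36e-09) and Dusp1 (2.47 ± 0.33, adjusted p = 4.12e-09) were among those higher. Their sum was 71.9 ± 2.18 against 21.2 ± 0.932 molecules per 10000. The myeloid markers summed to 1.68 ± 0.656 against 0.971 ± 0.317 and 0 of 10 passed limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 of 6 with edgeR; camera adjusted p = 0.236). The cAMP-responsive transcription factor gene Crem (2.37 ± 0.31, adjusted p = 3.97e-09), the receptor gene P2ry10 (2.47 ± 0.30, adjusted p = 2.14e-10) and Emb, a cell adhesion gene (at least 28.9-fold), rose. Dgat1, a gene of triglyceride synthesis, had 41 molecules against 2 (ratio 43.3, 95% interval 11.3 to 370). The chemokine receptor genes Cxcr4 (2.17 ± 0.32, adjusted p = 6.86e-08) and Ccr2 (1.37 ± 0.28, adjusted p = 0.000131) rose. Ccl5 (2.16 ± 0.34, adjusted p = 0.00117), Ifngr1 (1.40 ± 0.21, adjusted p = 1.11e-07), Icos (1.40 ± 0.28, adjusted p = 0.000115) and Klf2 (1.59 ± 0.36, adjusted p = 0.000634) were higher in lung as well.

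Interferon-stimulated genes fell with 12 of 25 lower (16 adjusted over the list alone; 6 on the common total; camera adjusted p = 8.25e-05). Ifi209 (-1.98 ± 0.35, adjusted p = 6.76e-06) and Slfn1 (-1.83 ± 0.39, adjusted p = 0.000258) were among them. Id2 (-2.23 ± 0.19, adjusted p = 1.35e-17), Fgl2 (-2.30 ± 0.26, adjusted p = 1.10e-11), Il7r (-1.65 ± 0.23, adjusted p = 1.83e-08), Gzmb (-1.85 ± 0.27, adjusted p = 1.06e-07) and the integrin gene of residency Itgae (1 molecule against 29, ratio 13.7, interval 2.28 to 561) fell. The Ly49 list was called down (2 of 5, 4 adjusted over the list alone; 2 on the common total; camera adjusted p = 0.0156), lost at an adjusted p = 0.276 with an estimated correlation. Tissue residency (6 higher and 4 lower of 17, the same counts adjusted over the list alone, 6 and 3 on the common total, with a median of -0.07), cytokine receptors (3 higher and 1 lower of 14, 3 and 3 adjusted over the list alone, 3 and 1 on the common total) and early stage genes (1 higher and 1 lower of 7, 2 and 1 adjusted over the list alone, 2 and 0 on the common total) were called up at a camera adjusted p = 0.0364 each. They were lost at an adjusted p = 0.249, an adjusted p = 0.276 and an adjusted p = 0.158 with an estimated correlation. Of the early stage genes the higher was Nr4a1 (15 molecules against 1) and the lower Itm2a (3 against 22). Nr4a1 is also in the immediate early and residency lists, and other lists hold 5 of the 7 tested early stage genes. Of 77 ribosomal protein genes 74 fell (43 on the common total), with a median of -0.95 (-0.48 on the common total).

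Of all genes 112 rose and 438 fell on the deposited values, and 160 rose and 151 fell on the common total, with 263 called in the same direction on both. In all 1241 had an unadjusted p under 0.05 (chance 256.9), and groups did not overlap for 25.4% (chance 10%). These 2 figures are on the deposited values as well, with a median log2 fold change of all genes of -0.29 (-0.04 on the common total). Part of their excess over chance can come from the scaling. In both subsets 46 of the same genes were higher in lung, where 5.91 are expected of unrelated lists, and 212 were lower, where 42.1 are expected, with a Pearson correlation of 0.400 and a Spearman correlation of 0.361 across genes. The lower lung total moved genes down in both subsets alike. On the common total 61 were higher in both (11 expected) and 80 lower (6.0 expected), with a Pearson correlation of 0.336 and a Spearman correlation of 0.301.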

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

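These tests were chosen only after the results were seen: the myeloid interaction count, the T cell receptor complex median, the myeloid and handling tests of the immediate early genes, and thinning for the lower genes, whose number of draws was raised from 1 to 20 and whose measure was changed from calls to fold changes after calls had been seen.

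Limma's interaction test called 168 genes, 136 with a positive and 32 with a negative interaction (3 libraries in each of 4 groups). The 10 with the smallest p were flagged, and each had a larger log2 fold change in lung than in thymus. The differences were 5.48 for Cd74 (adjusted p = 1.35e-12), 5.43 for Apoe (1.35e-12), 5.09 for H2-Aa (2.49e-11), 4.81 for Selenop (1.73e-10) and 4.56 for H2-Eb1 (1.61e-09). They were 4.37 for H2-Ab1 (9.57e-09), 4.26 for Mrc1 (1.04e-08), 4.26 for C1qc (1.43e-08), 4.27 for Cd14 (1.43e-08) and 4.20 for C1qb (1.57e-08). All 3 lung CD244-positive libraries lay above all 3 lung CD244-negative libraries for each gene. The thymus log2 fold change was 0.15 for Cd74, -0.65 for Selenop and 0 for the other 8. Fitted differences of genes at 0 in a group depend on the added 1. With edgeR on 9 libraries all but Selenop missed the threshold. Of these, the 8 with a thymus log2 fold change of 0 have no molecule in either thymus subset. A count model then has no thymus ratio to set against the lung ratio, so edgeR's interaction test cannot decide for them. For Cd74 the cause was not tested.

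A candidate source of the macrophage transcripts in lung CD244-positive libraries is RNA or cells of another type, macrophages being 1 hypothesis. All 10 tested myeloid markers rose, none of which another list holds and 3 of which had molecules in lung CD244-negative cells; in the CD244-positive libraries Cst3 had 29.3 ± 10.5, Mrc1 18.4 ± 4.53 and Lyz2 9.66 ± 2.57 units (SD, n = 3), and the 4 tested B cell list genes are MHC class II genes and Cd74, which macrophages share. A gate on TCRbeta and the CD1d tetramer is meant to leave macrophages out, but how far it did so was not tested. In the same libraries the 14 T cell receptor complex genes had a median log2 fold change of -0.75, with 12 below 0 (camera adjusted p = 0.0129 with an estimated correlation). Other RNA would lower these genes. Lower depth of the CD244-negative libraries was argued against by thinning, after which a median of 10 myeloid markers still rose (9 to 10 over 20 draws), and expression by CD244-positive cells of both tissues alike by the 10 called in limma's interaction (1 of 6 with edgeR) beside sums of 0.994 ± 0.0592 and 0.971 ± 0.317 molecules per 10000 in thymus CD244-positive and CD244-negative cells. Expression of these genes by lung CD244-positive cells alone was not tested and stays open.

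Immediate early genes were higher in lung in both subsets. RNA of myeloid cells was argued against for the part seen in lung CD244-negative cells, where 7 immediate early genes rose and 0 of 10 myeloid markers passed limma (0 at an unadjusted p under 0.05, 0 of 6 with edgeR), and lower depth by thinning, after which a median of 6 still rose (5 to 8). For the larger rise in CD244-positive cells, with 8 of 24 genes called in limma's interaction (1 of 19 with edgeR), RNA of myeloid cells and a response of the CD244-positive cells cannot be told apart, because the same libraries hold both signals. Handling of the lung during cell release could not be separated from tissue, since each tissue was handled in its own way, and the heat shock list was not called in lung CD244-negative cells (camera adjusted p = 0.721). A difference of the cells between tissues stays open as well, and was not tested.

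Genes lower in lung CD244-positive cells numbered 145. After scaling to the T cell receptor complex genes, 13 of the 141 outside the scaling genes stayed lower, among them Cxcr6, Gata3, Gimap3, Gimap6, Icos, Ly6a and Satb1, while their median log2 fold change went from -1.16 (SD 0.41) to -0.34 (SD 0.57) and the median of all tested genes from -0.01 to 0.55. The calls ended because the scaling moved all genes upward, so dilution of T cell RNA by other RNA and a lower level in these cells cannot be told apart for the rest. After thinning, the median log2 fold change of the 145 was -1.14 (SD 0.47, and -1.17 to -1.10 over 20 draws) against -1.16 (SD 0.42) before, with 0 above 0. This argued only against a shift of these fold changes by unequal depth. The 145 were picked by calls in the same libraries, and thinning changes the shallow CD244-negative libraries little. It therefore cannot decide whether sampling error in those libraries added to the calls. The number still called fell to 70 (64 to 82) as the median standard error went from 0.28 to 0.36.

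Other splits of the libraries were fitted in the same way. The splits of 6 libraries numbered 10, too few for a share under 0.05: the real count was 21 in thymus (highest other 1), 433 in lung (0), 765 for tissue in CD244-positive cells (0) and 550 in CD244-negative cells (0), with 1 split, the real one, reaching each. Over both tissues 1 of 100 splits, the real one, reached the real count of 242 (highest other 202), which argued against chance for the grouping of the 12 libraries together. Of the 10 splits that kept the real lung groups 1 reached it, too few to judge the thymus grouping. The split with 202 kept the real lung groups, and those that broke them reached at most 3, so that the count rested on the lung libraries and the share does not show a difference in both tissues. For the interaction 10 of 100 reached 168 (highest other 242), and these splits did not exclude chance. All 10 kept the real lung groups, and those that broke them reached at most 3. Because most of the leading genes have no molecule in thymus, regrouping the thymus libraries could not change their interaction, so this share does not measure chance for them.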

How the results depend on the processing

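The common total, thinning, T cell receptor complex scaling, lung CD244-positive library 1 alone and edgeR were chosen after the data were seen. Of 106 calls named for their small p, 85 (edgeR) to 106 stayed past the threshold in the same direction under each setting that gave all 6 comparisons. Counts within 1.5 times the reported count are not listed, and the cause of the changes was not tested, except that edgeR, the stricter filter and the single library had fewer genes or libraries. The single library is assumed to vary like the other groups.

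In thymus the count of 21 was 12 with edgeR and 10 to 21 with each library left out. In lung the count of 433 was 250 with the stricter filter, 263 thinned, 1214 with T cell receptor complex scaling, 162 with lung CD244-positive library 1 alone, 180 with edgeR and 327 to 422 with each library left out. Over both tissues the count of 242 was 157, 136, 827, 120 and 76 in the same order, and 199 to 278. The interaction count of 168 was 104, 78, 331, 62 and 21 in the same order, and 122 to 198. For tissue in CD244-positive cells the count of 765 was 453 with the stricter filter, 365 with lung CD244-positive library 1 alone, 299 with edgeR and 592 to 801 with each library left out. In CD244-negative cells the count of 550 was 295 with quantile normalization, 311 on the common total, 290 thinned, 219 with edgeR and 390 to 531 with each library left out.

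With an estimated correlation, list calls went from 11 to 6 in lung, 8 to 4 in the interaction, 9 to 5 for tissue in CD244-positive cells (19 with fry) and 7 to 2 in CD244-negative cells. The Pearson and Spearman correlations between tissues, 0.123 and 0.0835, were 0.0932 and 0.0541 without a filter and 0.225 and 0.117 with the stricter filter, and Pearson's was 0.0930 thinned. Genes higher in both tissues went from 13 to 8 on the common total, 7 thinned and 6 to 12 with each library left out, and genes lower in both from 3 to 1 thinned and 0 to 3 with each library left out. With T cell receptor complex scaling Pabpc1 (0.24), Tmsb10 (0.25), Ly6c2 (0.023) and Cd3d (0.059) turned to positive log2 fold changes in lung and Eef1a1 (0.32) over both tissues. Hspa8 turned positive for tissue in CD244-positive cells with quantile normalization (0.36) and edgeR (0.20), and in CD244-negative cells with quantile normalization (0.18).

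With the replicate number as a block the counts were 19, 428, 239, 161, 750 and 525 in the order of the comparisons, and the list counts were unchanged. Replicate numbers did not pair libraries: same-number pairs across groups correlated at -0.119 to 0.0749 (18 pairs, 578 genes) and other pairs at -0.146 to 0.117 (36 pairs), and 1 of 12 libraries had its best match under its own number. ERCC scaling and the ratio of endogenous to spike-in RNA were not run because the table has 0 ERCC rows, and DESeq2 was not run because its values are not counts. Depth limited genes near 3 molecules, which was 1.80 to 1.95 units in lung CD244-negative libraries and at most 1.42 in the others.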

Other observations

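Single members of the tissue residency list moved both ways between tissues. The residency list summed to 31.4 ± 1.28 and 32.6 ± 3.60 molecules per 10000 in lung CD244-positive and CD244-negative cells, against 22.4 ± 2.85 and 20.0 ± 0.598 in thymus (SD, n = 3). Rgs2, a regulator of G protein signalling, rose in lung CD244-negative cells (log2 fold change 1.38 ± 0.25 SE, limma adjusted p = 1.64e-05), as did the transcription factor gene Bhlhe40 (1.80 ± 0.39, adjusted p = 0.000462). Itgae fell in lung CD244-positive cells (-2.13 ± 0.38, adjusted p = 6.88e-06), and Inpp4b fell in both subsets (-1.79 ± 0.27, adjusted p = 9.22e-08 in CD244-positive, -1.55 ± 0.27, adjusted p = 6.01e-06 in CD244-negative cells). In CD244-positive cells 5 of 17 members were higher and 4 lower (5 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.268). Its call in CD244-negative cells was lost with an estimated correlation.

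Of 11 tested heat shock genes, limma called 2 higher and 2 lower in lung CD244-positive cells (2 and 2 adjusted over the list alone; 2 and 0 on the common total), and 1 higher and 2 lower in lung CD244-negative cells (1 and 3 adjusted over the list alone; 2 and 0 on the common total). The 2 lower in CD244-negative cells, Hspa8 and Hspe1, named after their values were seen, both missed the threshold without thymus CD244-negative library 2 (adjusted p = 0.0924 and 0.173) or 3 (0.0845 and 0.111), Hspa8 without lung CD244-negative library 2 (0.266) and Hspe1 without lung CD244-negative library 1 (0.200). Hspa1b, an inducible chaperone gene with no molecule in thymus, was at least 13.8-fold higher in lung CD244-positive and at least 5.99-fold higher in lung CD244-negative cells. The constitutive Hspa8 had a log2 fold change of -0.50 ± 0.16 in CD244-positive cells (adjusted p = 0.0171), a call lost in 5 other settings. It missed the threshold without thymus CD244-positive library 1 (adjusted p = 0.189), thymus CD244-positive library 3 (0.0855) or lung CD244-positive library 3 (0.0592), and its log2 fold change turned to 0.36 with quantile normalization and 0.20 with edgeR. The list was not called in either subset (camera adjusted p = 0.345 and 0.721). Zeb2, a transcription factor gene, had 41 molecules in lung CD244-positive and none in lung CD244-negative libraries, at least 8.81-fold more. It had 1 molecule in the thymus CD244-positive libraries. The lung libraries that held it were those in which the myeloid markers rose, so its cell of origin cannot be told from these values. NKT17 markers, with 3 tested members and no list test, summed to 6.51 ± 2.36 and 5.78 ± 1.61 molecules per 10000 in lung CD244-positive and CD244-negative cells against 1.47 ± 0.262 and 1.38 ± 0.346 in thymus.

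Measures of the spread between replicates ranked the groups differently. The chi-square per degree of freedom between replicate pairs was 2.28 to 2.35 in lung CD244-positive, 1.22 to 1.46 in lung CD244-negative and 1.14 to 1.33 in thymus libraries. The Pearson correlation of log2 values across genes was 0.814 to 0.831 between lung CD244-positive, 0.777 to 0.783 between lung CD244-negative and 0.855 to 0.874 between thymus replicates. Counting error also lowers this correlation, and the lung CD244-negative libraries held the fewest molecules (29696 to 32196). The limma model used 1 spread per gene for all 4 groups, so p-values of comparisons with lung CD244-positive libraries may be too small. Rn45s, a ribosomal RNA precursor named after its values were seen, took 7.05% ± 0.540, 6.09% ± 0.362, 8.48% ± 0.863 and 8.83% ± 0.909 of molecules in thymus CD244-positive, thymus CD244-negative, lung CD244-positive and lung CD244-negative libraries (SD, n = 3).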
